A study of Pseudomonas putida DOT-T1E with 18 samples.

How the data were processed

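RNA-seq values of 18 libraries of Pseudomonas putida DOT-T1E were analysed, 2 for the LB control and 2 for each of 8 antibiotics. Per the labels, single colonies were grown overnight in LB at 30 °C, diluted and split into separate flasks, and the antibiotic was added at an OD600 of 0.5 for 1 h. RNA was extracted with Trizol and treated with DNase I, and libraries were made by standard Illumina protocols. The aligner, the quantification program and the strandedness of the libraries are not given in the sources used here.

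The deposited files hold 1 score per row, a whole number that the authors scaled so that the upper quartile of the annotated genes is nearly the same in each library (107 to 117.5 over the nonzero genes of the 17 libraries used, 123 in kanamycin 2). Each file has the same 7482 rows, of which 5803 are annotated genes and 1679 are predicted RNAs, 1493 of them listed as antisense to named genes. The score is not a count, and whether it is divided by gene length is not stated. Library totals differed by 2.66 times. Reads behind a value are unknown, so no counting interval is given. The 2 kanamycin files differed by 17 in all rows. The lowest value of kanamycin 2 was 17, while kanamycin 1 had 207 rows at 0, so kanamycin 1 was kept and the group was treated as a single library.

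Rows with the same antisense label at most 10 rows apart were averaged, which gave 1112 antisense-listed RNAs, 255 of them from more than 1 row. Of the 7101 features, 10 rRNA features were left out (8 genes and 2 antisense-listed RNAs), and features with a mean under 5 were filtered out. This left 7011 features, 5715 genes, 1110 antisense-listed RNAs and 186 predicted RNAs without a name. The reference table covers another strain with 5572 rows and none of its identifiers matched the locus tags, so names were taken from the files. Of the names in antisense labels 691 are gene symbols and 674 locus tags. Among the annotated genes 140 products carry a symbol and 1648 are hypothetical. Genome coordinates are not in the files and were not used here.

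Each antibiotic was compared with the LB control, and gentamicin with kanamycin, 9 comparisons in all. The plan, made before the data were examined, named a count-based test for counts and limma for normalised values, and the files called for limma. Values were fitted as log2(value + 1) with a mean for each of the 9 groups in 17 libraries (8 residual degrees of freedom), with limma's moderated test (eBayes with trend, two-sided). Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the 7011 features of each comparison. The share of calls with at least a 2-fold change is given beside them. The replicate number of the labels was not used as a block. Residuals of libraries with the same number correlated between -0.04 and 0.09 over the 28 pairs of groups, under the limit of 0.1 set for pairing.

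Gene lists were fixed as 24 lists of symbols and product names, and 19 members caught by an ambiguous pattern were removed before any test. Lists were tested with camera (limma) on antisense-listed RNAs (20 lists) and on annotated genes (23 lists) separately, with a preset correlation of 0.01 and a minimum of 5 members, and adjusted over the 344 tests. A second run estimated the correlation for each list. Of the 28 calls made with the preset correlation, 0 were made with the estimated one, where the lowest adjusted p was 0.997. Counts "adjusted over the list alone" used a Benjamini-Hochberg adjustment over the list's members.

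Named features were chosen by rule. For each comparison it took the 8 largest increases and the 8 largest decreases among calls with a known product, all libraries of the group beyond all libraries of the reference and a mean of at least 10 in the higher group, with at most 2 neighbours. It added up to 3 called members of each called list in the direction of the list, and the fixed genes recA, lexA, recN, gyrA, gyrB, rpoB, rpoC, rpsL, rpsE, ampC, ttgA, ttgB, ttgC, ttgR, ttgD, ttgG, oprH, groEL, lon, katA and ahpC where the files name them. The report gives a selection of the features so named, and one result is not reported here.

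Responses to pairs of antibiotics were compared by Pearson's r over all features, by the covariance and by shared calls, with the number expected for independent lists. Because all 28 pairs share the LB control, 20 simulated sets of unchanged groups gave an estimate of the correlation that shared controls produce. Their noise was drawn from each feature's moderated spread over all groups. The correlations were also computed with each antibiotic of a pair against its own LB control library, in both assignments. Rank correlations between libraries were Spearman's rho over the antisense-listed RNAs and over the annotated genes.

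The fit was tested on simulated data with this design, 10 draws with 200 changed features each. With 2 libraries against 2, a 2-fold change was recovered in 7.31%, a 4-fold change in 41.9% and an 8-fold change in 65.3% of cases, with 7.42% false calls. With 1 library against 2, as for kanamycin, these were 1.34%, 20% and 47.3%, with 4.41% false calls. A list moved in the simulation was called by camera in 10 of 10 draws and an unmoved one in 0 of 10, at an unadjusted p under 0.05. Noise was drawn from each feature's moderated spread, which the test itself uses, so recovery may be overstated and false calls understated. The simulated features varied independently. These draws therefore cannot show how camera acts on lists whose members vary together.

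Alternative settings chosen in advance were quantile normalization, pseudocounts of 0.1 and 10, no filter, rRNA kept, the replicate number as a block, only the libraries of the comparison, camera with an estimated correlation, features above the lowest quartile by mean value for the correlations, and leaving out each library in turn. Values centred on the median antisense-listed RNA of each library, rows tested separately, kanamycin as the mean of its files, and other scalings, omitted controls and separate controls for the correlations were added after the data were seen. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.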

Results

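RNA was sequenced from Pseudomonas putida DOT-T1E, a solvent-tolerant soil bacterium, grown in LB medium at 30 °C without an antibiotic (LB control) or with 1 of 8 antibiotics. Each antibiotic was added at an OD600 of 0.5, at a concentration the labels call sub-lethal, and the cultures grew for 1 h more. For the LB control the sample labels give neither an OD600 nor a further hour of growth. The comparisons with LB control may therefore include a difference in growth stage. In µg/ml, rifampicin was given at 500, ampicillin and spectinomycin at 300, chloramphenicol at 150, tetracycline at 4, gentamicin at 2, kanamycin at 1 and ciprofloxacin at 0.5. The design compares each antibiotic with the LB control to map its effect on the transcriptome. Each of the 9 groups was deposited as 2 libraries, 18 in all. The kanamycin libraries differed by exactly 17 in each of the 7482 rows. They were counted as 1 sample, and kanamycin 1 was used, which left 17 libraries. In the other pairs of libraries the commonest difference covered at most 4.70% of the rows. Means are given ± SD with n = 2 throughout, except for kanamycin, whose single library has no SD. The labels do not say that the libraries of a group came from separate overnight cultures, so the spread between them may be technical. The p-values use a spread per feature pooled over the 9 groups, not that of the compared libraries alone. As described below for pairs of antibiotics, this spread fell short of the difference between the LB control libraries. The p-values against LB control may therefore be too small. The values of a library summed to between 18671664 and 49712865 normalised units. These are scaled values and not reads, so the depth behind each value is unknown.

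The files list 5803 annotated genes, 1493 predicted RNAs named as antisense to 1 or more genes and 186 predicted RNAs with no name. An RNA listed antisense to recN is written as-recN, and one listed antisense to recX and recA as-recX/recA. A locus tag alone, such as T1E_0244, stands for the row of the annotated gene. Antisense-listed RNAs held 78.5% and 80.8% of the units in the 2 LB control libraries. The genes' own rows were low even for genes of the translation apparatus. The 53 ribosomal protein genes had median values of 20 and 13 in the 2 LB control libraries, where the median of all genes was 50 in both. The 14 RNAs listed antisense to ribosomal protein genes had medians of 20095 and 21458.5. For the 66 tRNA genes the medians were 17 and 0, and for the 29 RNAs listed antisense to tRNA genes 24166 and 35885. No label or file header says how strand was assigned. Each value is therefore reported under the name the files give.

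The rank order of antisense-listed RNAs lay close to that of the LB control in some groups and far from it in others. Spearman's rho across these RNAs was 0.918 between the LB control libraries and 0.936 to 0.957 between LB control and ampicillin. It was 0.756 to 0.784 for chloramphenicol and 0.772 to 0.818 for kanamycin. Spectinomycin had 0.415 to 0.443. Ciprofloxacin (0.081 to 0.148), tetracycline (0.151 to 0.230), rifampicin (0.125 to 0.160) and gentamicin (0.121 to 0.173) stood farthest away. Rifampicin and gentamicin had 0.856 to 0.883 with each other. The lowest value within a group was 0.815, for tetracycline. Over the annotated genes the groups lay closer together. The rank correlation with LB control was 0.586 to 0.666 for ciprofloxacin, 0.612 to 0.679 for tetracycline, 0.648 to 0.740 for rifampicin, 0.660 to 0.722 for gentamicin and 0.706 to 0.752 for spectinomycin. It was 0.706 to 0.836 for chloramphenicol, 0.782 to 0.842 for kanamycin and 0.823 to 0.881 for ampicillin. Within groups the rank correlation was 0.796 for LB control, 0.745 for chloramphenicol and 0.692 for tetracycline. These correlations are across RNAs, which are not independent replicates, and carry no p. Here and in the comparisons below, the effect of an antibiotic cannot be told apart from a batch that holds whole groups. Several lists and RNAs below rose or fell with more than 1 antibiotic, so a change is not particular to the antibiotic it is given under.

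**Figure D1:**
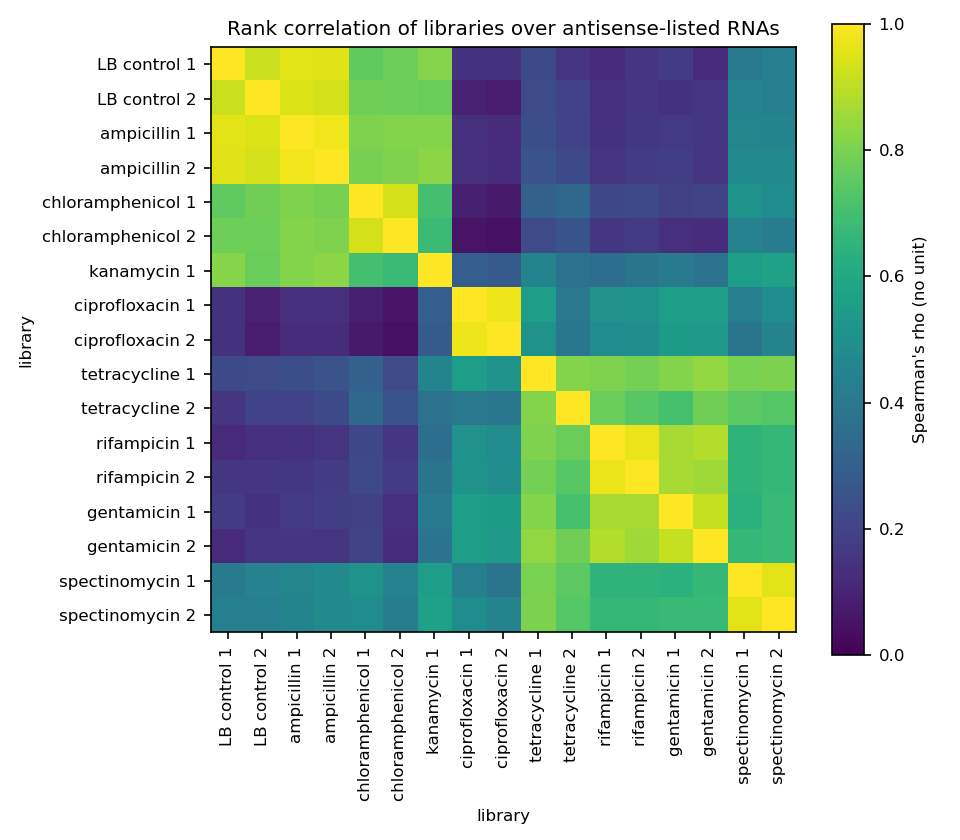
Spearman's rho (no unit, colour scale from 0 to 1) between the 17 libraries over the antisense-listed RNAs, with a library on each axis. LB control and ampicillin reach 0.936 to 0.957 with each other, and ciprofloxacin only 0.081 to 0.148 with LB control.

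Called features ranged from 3 with ampicillin to 1607 with ciprofloxacin, of 7011 tested (limma on log2(value + 1), Benjamini-Hochberg adjusted p under 0.05). The numbers were 81 for kanamycin, 155 for chloramphenicol, 864 for spectinomycin, 1245 for gentamicin, 1285 for rifampicin and 1427 for tetracycline. As a class, antisense-listed RNAs stood higher than in the LB control under the authors' scaling. Their median log2 fold change was 1.03 with tetracycline, 0.89 with gentamicin, 0.86 with rifampicin and 0.70 with spectinomycin. The medians of the annotated genes were -0.12, 0.05, 0.04 and 0.07. With ciprofloxacin the antisense-listed RNAs had 0.30 and the genes 0.19, with kanamycin 0.37 and 0.08, with chloramphenicol 0.19 and -0.11, and with ampicillin 0.15 and 0.14. Changes of gene lists are given relative to the median of antisense-listed RNAs for that reason. Many of the 1110 antisense-listed RNAs tested were also called. With ciprofloxacin 427 rose and 299 fell, with gentamicin 528 and 139, with rifampicin 519 and 153 and with spectinomycin 420 and 92. With chloramphenicol 76 rose and 16 fell, and with kanamycin 44 and 10. A list with many increases is therefore not by itself set apart from the class. The libraries also differed in composition. RNAs listed antisense to tRNA genes held 28.4% and 28.3% of the units in LB control, 28.3% and 25.9% with ampicillin and 31.3% and 32.4% with chloramphenicol, and rRNA held 15.8% and 19.5%, 18.7% and 18.5% and 15.3% and 14.9%. Quantile normalization moved the medians of both classes to between -0.12 and 0.09. The share of increases among the calls depended on the scaling, and is given for each antibiotic with quantile normalization and with log2 values centred on the median antisense-listed RNA of each library.

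**Figure D2:**
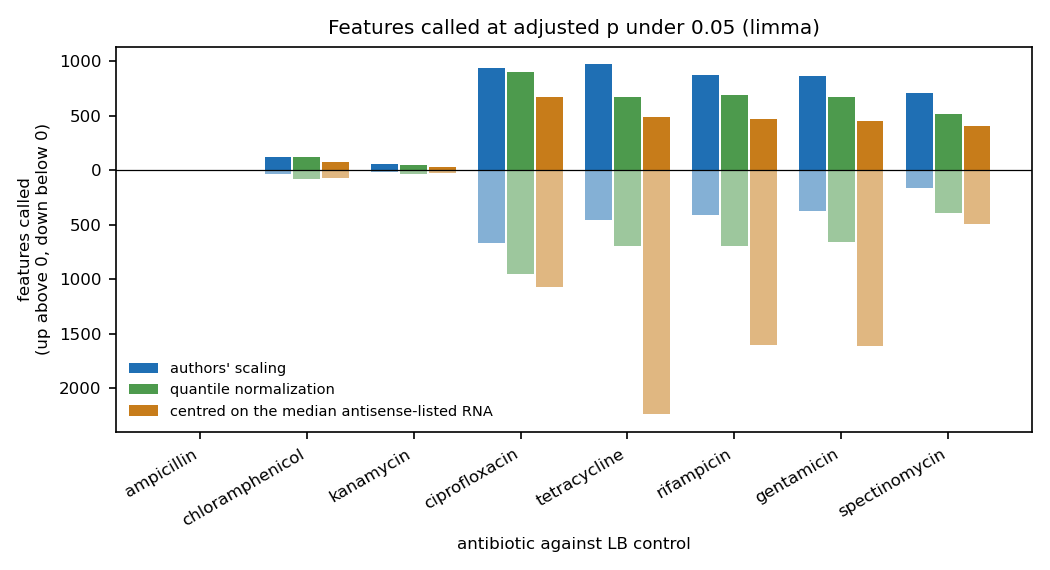
Features called for each antibiotic against LB control (x axis) as their number (y axis, increases above 0 and decreases below it), with bars for the authors' scaling, quantile normalization and centring on the median antisense-listed RNA. With tetracycline, 972 increases and 455 decreases became 493 and 2237 after centring.

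Ciprofloxacin, a fluoroquinolone that inhibits DNA gyrase and topoisomerase IV, came with higher RNAs antisense-listed to some DNA repair genes. as-recN, at a gene of double-strand break repair, stood at 9417 ± 597 against 465 ± 54.4 (log2 fold change 4.34, adjusted p = 4.97e-07). as-recX/recA, at the locus of the recombinase that starts the SOS response and of its modulator, stood at 21646.5 ± 452 against 4440.5 ± 407 (log2 fold change 2.29, adjusted p = 8.32e-06). as-lexA-1, at the locus of the SOS repressor, stood at 4234 ± 1019.6 against 1556 ± 8.49 (log2 fold change 1.42, adjusted p = 0.0024), while the row of LexA repressor 1 (T1E_1218) fell from 450.5 ± 40.3 to 204.5 ± 3.54 (log2 fold change -1.13, adjusted p = 0.00891). as-gyrA, at the locus of a gyrase subunit, rose to 14322 ± 383 from 2963 ± 408 (log2 fold change 2.28, adjusted p = 1.27e-05). Of the SOS and DNA repair list, 7 of 11 (8 adjusted over the list alone) antisense-listed RNAs rose and 0 fell, 6 after quantile normalization and 6 after centring (where 0 and 2 fell), and the list as a whole was not called (camera adjusted p = 0.311). RNAs listed antisense to peptidoglycan and beta-lactam response genes rose in 21 of 25 (21 adjusted over the list alone) cases, 18 after quantile normalization and 20 after centring, and 1 fell (median relative log2 fold change 1.99, camera adjusted p = 7.64e-04). They included as-mrdB, at a rod-shape gene, at 7252 ± 354 against 165 ± 28.3 (log2 fold change 5.46), and as-ponA, at a penicillin-binding protein gene, at 8371 ± 214 against 319.8 ± 18.0 (log2 fold change 4.71). For outer membrane and lipopolysaccharide genes 13 of 13 (13 adjusted over the list alone) rose, 9 after quantile normalization and 9 after centring (median relative log2 fold change 1.77, camera adjusted p = 0.00635), among them as-lpxB, of lipid A synthesis, with a log2 fold change of 4.26. For the TCA cycle and central carbon list 18 of 23 (19 adjusted over the list alone, where 3 fell) rose, 17 after quantile normalization and 18 after centring (where 3 and 3 fell), and 1 fell (median relative log2 fold change 1.89, camera adjusted p = 0.00795). Each of these 3 list calls had adjusted p = 0.997 with an estimated correlation. The same libraries held 22.6% and 29.2% of their units in rRNA and 4.27% and 3.37% in RNAs listed antisense to tRNA genes, shares that were not tested.

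Among the features that fell with ciprofloxacin, as-phoB, at the locus of the regulator of the phosphate starvation response, went from 8696 ± 875 to 157 ± 6.01 (log2 fold change -5.78, adjusted p = 1.23e-07). as-pstS, at the locus of a phosphate-binding protein, fell from 3560.3 ± 514 to 119.7 ± 21.2 (log2 fold change -4.89, adjusted p = 1.70e-07). as-mgtB/T1E_0389, at a magnesium transporter locus, fell from 32483.5 ± 7015 to 1038.5 ± 199 (log2 fold change -4.96). Its neighbour by locus tag, the major facilitator transporter T1E_0388, had a log2 fold change of -5.30. as-lon/hupB, at the locus of a protease and a nucleoid protein, fell with a log2 fold change of -1.87. Of the toluene efflux genes, as-ttgB rose, at 3993 ± 190.1 against 271 ± 147 (log2 fold change 3.99) as did the row of the repressor TtgR (T1E_0244), at 16503.5 ± 1453 against 2595 ± 851 (log2 fold change 2.71, adjusted p = 1.74e-05). The product TtgB is given to 3 locus tags (T1E_0242, T1E_0107 and T1E_5468), and how reads were divided between them is not stated. In all, 940 features rose and 667 fell, of which 903 and 634 changed at least 2-fold. Increases made up 58.5% of the calls, 48.8% of 1859 after quantile normalization and 38.6% of 1750 after centring. The call of T1E_1218 ended without LB control 2 (adjusted p = 0.0628) or without ciprofloxacin 1 (0.0508).

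**Figure D3:**
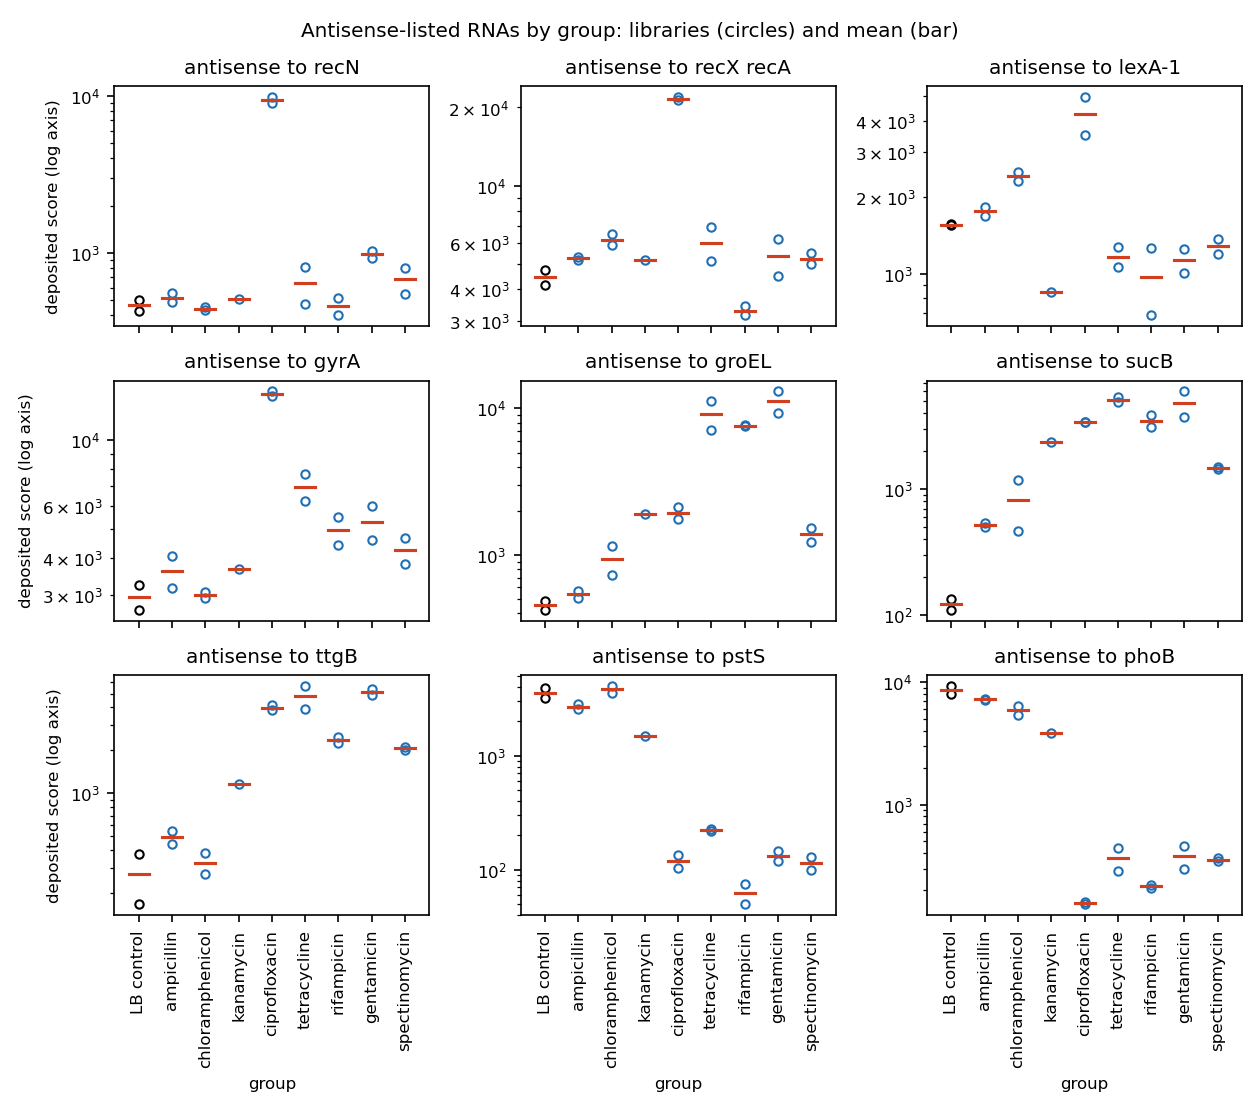
Deposited scores (y axis, log scale, 1 panel per RNA) of 9 antisense-listed RNAs in the 9 groups (x axis), with each library as a circle and the group mean as a bar. RNAs antisense-listed to recN and recX recA reach 9417 and 21646.5 with ciprofloxacin against 465 and 4440.5 in LB control, while those to pstS and phoB lie at 62.5 to 378 with ciprofloxacin, rifampicin, gentamicin and spectinomycin, against 3560.3 and 8696 in LB control.

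Tetracycline, which blocks the binding of aminoacyl-tRNA to the ribosome, came with higher RNAs at loci of respiration and the TCA cycle. RNAs listed antisense to ATP synthase and respiratory chain genes rose in 20 of 20 (20 adjusted over the list alone) cases, 18 after quantile normalization and 19 after centring (median relative log2 fold change 1.96, camera adjusted p = 5.72e-04). as-nuoM/nuoN, at NADH dehydrogenase subunits, stood at 5657.5 ± 1381 against 108 ± 25.5 (log2 fold change 5.70, adjusted p = 8.77e-07). as-sucB, at a subunit of 2-oxoglutarate dehydrogenase, stood at 5138 ± 351 against 122 ± 17.0 (log2 fold change 5.39, adjusted p = 1.34e-06), and 21 of 23 (22 adjusted over the list alone) of the TCA cycle and central carbon list rose, 17 after quantile normalization and 17 after centring, while 1 fell (median relative log2 fold change 1.21, camera adjusted p = 0.00732). At chaperone loci, as-groEL, at 9220.2 ± 2972 against 453.5 ± 44.5 (log2 fold change 4.31, adjusted p = 1.34e-06), and as-grpE, at 7269 ± 2348 against 105.5 ± 121 (log2 fold change 6.80), rose. The list of chaperones and proteases had 14 of 17 (14 adjusted over the list alone) increases, 9 after quantile normalization and 9 after centring (where 1 and 1 fell), and was not called (camera adjusted p = 0.0824). The outer membrane list had 13 of 13 (13 adjusted over the list alone) increases, 11 after quantile normalization and 11 after centring (median relative log2 fold change 1.53, camera adjusted p = 0.00924), and the peptidoglycan list 21 of 25 (23 adjusted over the list alone), 17 after quantile normalization and 19 after centring, beside 1 decrease (median relative log2 fold change 1.13, camera adjusted p = 0.0212). Ribosomal protein loci rose in 12 of 14 (14 adjusted over the list alone) cases, 8 after quantile normalization and 9 after centring (median relative log2 fold change 1.41, camera adjusted p = 0.0492), with as-rpsT at 274859 ± 151294 against 33202 ± 6237. Each of these 5 list calls had adjusted p = 0.997 with an estimated correlation. The ribosomal protein call was also lost after quantile normalization (adjusted p = 0.192), without LB control 1 (0.145) and without tetracycline 2 (0.133), and the peptidoglycan call without tetracycline 1 (0.0954). The replicate number as a block ended the ribosomal protein call too. With tetracycline rRNA held 20.5% and 29% of the units and RNAs listed antisense to tRNA genes 8.77% and 7.4%.

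At toluene efflux loci, as-ttgB stood at 4773 ± 1242 against 271 ± 147 (log2 fold change 4.22, adjusted p = 2.56e-06), whereas the rows of the pump genes T1E_0241 (TtgC, log2 fold change -2.18) and T1E_0107 (TtgB, log2 fold change -1.58) fell. The call of T1E_0107 ended without LB control 2 (adjusted p = 0.0544). as-lon/hupB stood at 96826 ± 30052 against 21331.5 ± 1326 (log2 fold change 2.15, adjusted p = 2.13e-04), the reverse of its direction with ciprofloxacin. T1E_0388 fell from 1260 ± 59.4 to 37.5 ± 37.5 (log2 fold change -5.50). The increases of as-gyrA (log2 fold change 1.23) and of the TtgR row T1E_0244 (1.62) were calls under the authors' scaling only. After quantile normalization they had adjusted p of 0.491 and 0.137, and after centring 0.438 and 0.0628. In all, 972 features rose and 455 fell, of which 922 and 423 changed at least 2-fold. Increases made up 68.1% of the calls, 49.2% of 1374 after quantile normalization and 18.1% of 2730 after centring. With only the 4 libraries of the comparison in the fit, 388 features were called, and the calls of as-grpE (adjusted p = 0.0576), as-rpsT (0.0817), as-lon/hupB (0.0713), T1E_0388 (0.0539), T1E_0241 (0.109) and T1E_0107 (0.155) ended.

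Rifampicin, an inhibitor of RNA polymerase, came with higher RNAs at chaperone loci, as did tetracycline and gentamicin. RNAs listed antisense to heat shock chaperones and proteases rose in 15 of 17 (15 adjusted over the list alone) cases and 0 fell, 13 after quantile normalization and 13 after centring (where 1 and 1 fell) (median relative log2 fold change 1.54, camera adjusted p = 0.0121). as-htpG stood at 13531 ± 1578 against 350.5 ± 158 (log2 fold change 5.34, adjusted p = 8.55e-07), as-dnaK at 4425.5 ± 1149 against 191 ± 53.7 (log2 fold change 4.53, adjusted p = 6.56e-06) and as-groEL at 7645.5 ± 136 against 453.5 ± 44.5 (log2 fold change 4.08, adjusted p = 1.29e-06). The respiratory chain list rose in 20 of 20 (20 adjusted over the list alone) cases, 19 after quantile normalization and 18 after centring (median relative log2 fold change 1.65, camera adjusted p = 7.64e-04), the TCA cycle list in 19 of 23 (20 adjusted over the list alone, where 2 fell), 17 after quantile normalization and 17 after centring (where 3 and 3 fell) (median relative log2 fold change 1.60, camera adjusted p = 0.00924), the outer membrane list in 13 of 13 (13 adjusted over the list alone), 11 after quantile normalization and 11 after centring (median relative log2 fold change 1.76, camera adjusted p = 0.0107), and the peptidoglycan list in 21 of 25 (23 adjusted over the list alone), 17 after quantile normalization and 17 after centring, with 1 decrease (median relative log2 fold change 1.22, camera adjusted p = 0.0121). Each of these 5 list calls had adjusted p = 0.997 with an estimated correlation. as-putP, at the proline permease gene, stood at 13875 ± 1144 against 249 ± 17.3 (log2 fold change 5.79, adjusted p = 5.04e-08), and as-nuoM/nuoN at 6154 ± 173 against 108 ± 25.5 (log2 fold change 5.84, adjusted p = 3.63e-07). Of the units in the rifampicin libraries, rRNA held 38% and 30.7% and RNAs listed antisense to tRNA genes 2.66% and 3.57%.

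Among the features that fell with rifampicin, as-pstS went from 3560.3 ± 514 to 62.5 ± 18.1 (log2 fold change -5.83, adjusted p = 7.61e-08), as-phoB from 8696 ± 875 to 216 ± 8.84 (log2 fold change -5.32, adjusted p = 8.45e-08), and as-T1E_2661, at a phosphate transporter gene, from 4472.5 ± 531 to 104.5 ± 13.4 (log2 fold change -5.41, adjusted p = 2.81e-07). The rows of the polymerase genes T1E_1935 and T1E_1936, the beta subunits, were not called, at 34 ± 12.7 against 51.5 ± 3.54 (adjusted p = 0.539) and 12.5 ± 0.71 against 37.5 ± 10.6 (adjusted p = 0.123). as-recX/recA stood at 3299 ± 188 against 4440.5 ± 407 and was not called (log2 fold change -0.43, adjusted p = 0.232). The call of as-gyrA (log2 fold change 0.74, adjusted p = 0.0422) turned to -0.12 after quantile normalization and -0.16 after centring, neither of them a call. It also ended with a pseudocount of 10 (adjusted p = 0.0506), with only the 4 libraries of the comparison (0.11) and without LB control 1 (0.0562), LB control 2 (0.235), rifampicin 1 (0.063) or rifampicin 2 (0.241). In all, 873 features rose and 412 fell, of which 843 and 391 changed at least 2-fold. Increases made up 67.9% of the calls, 49.9% of 1390 after quantile normalization and 22.9% of 2078 after centring.

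Gentamicin, an aminoglycoside that causes misreading at the ribosome, came with higher RNAs at loci of respiration and carbon metabolism. as-T1E_2822, at a quinoprotein glucose dehydrogenase gene, stood at 7783 ± 747 against 102 ± 17.4 (log2 fold change 6.24, adjusted p = 1.33e-08). as-nuoM/nuoN stood at 8536.5 ± 549 against 108 ± 25.5 (log2 fold change 6.31, adjusted p = 3.54e-07) and as-putP at 14694 ± 1408 against 249 ± 17.3 (log2 fold change 5.87, adjusted p = 3.62e-08). The respiratory chain list rose in 19 of 20 (20 adjusted over the list alone) cases, 19 after quantile normalization and 18 after centring (median relative log2 fold change 2.26, camera adjusted p = 3.55e-04), and the TCA cycle list in 19 of 23 (21 adjusted over the list alone, where 1 fell), 18 after quantile normalization and 17 after centring (where 1 and 1 fell) (median relative log2 fold change 1.71, camera adjusted p = 0.005). Chaperone and protease loci rose in 14 of 17 (15 adjusted over the list alone) cases, 13 after quantile normalization and 12 after centring (where 1 and 1 fell) (median relative log2 fold change 1.22, camera adjusted p = 0.0289), led by as-grpE, as-htpG and as-groEL, the last at 11161 ± 2674 against 453.5 ± 44.5 (log2 fold change 4.60, adjusted p = 6.11e-07). Outer membrane loci rose in 13 of 13 (13 adjusted over the list alone) cases, 11 after quantile normalization and 11 after centring (median relative log2 fold change 1.67, camera adjusted p = 0.00891), and peptidoglycan loci in 22 of 25 (23 adjusted over the list alone), 18 after quantile normalization and 18 after centring, with 1 decrease (median relative log2 fold change 1.41, camera adjusted p = 0.00891). Each of these 5 list calls had adjusted p = 0.997 with an estimated correlation, and the chaperone call was also lost without LB control 1 (adjusted p = 0.0961). The share of rRNA in these libraries was 30.7% and 32.1%, and that of RNAs listed antisense to tRNA genes 3.82% and 3.1%.

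as-pstS fell with gentamicin from 3560.3 ± 514 to 133 ± 20.3 (log2 fold change -4.74, adjusted p = 3.55e-07), and as-phoB from 8696 ± 875 to 378 ± 112 (log2 fold change -4.55, adjusted p = 3.54e-07). as-ttgB stood at 5148 ± 389 against 271 ± 147 (log2 fold change 4.36, adjusted p = 2.29e-06). The calls of as-recN (log2 fold change 1.08), as-gyrA (0.83) and the TtgR row T1E_0244 (1.15) were lost under both other scalings, and as-gyrA turned to -0.046 after quantile normalization and -0.12 after centring. The call of as-recN ended too without LB control 1 (adjusted p = 0.099), gentamicin 1 (0.0565) or gentamicin 2 (0.0991). Those of as-gyrA and T1E_0244 ended without LB control 2 (adjusted p = 0.17 and 0.149) or gentamicin 2 (0.178 and 0.0895). In all, 870 features rose and 375 fell, of which 822 and 351 changed at least 2-fold. Increases made up 69.9% of the calls, 50.7% of 1337 after quantile normalization and 22.1% of 2068 after centring. With only the 4 libraries of the comparison in the fit, 736 features were called, and as-recN, as-gyrA and T1E_0244 were not (adjusted p = 0.0549, 0.143 and 0.0996).

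Spectinomycin, which blocks translocation of the ribosome, came with higher RNAs at loci of respiration and the cell envelope. as-putP stood at 10149.8 ± 1389.8 against 249 ± 17.3 (log2 fold change 5.34, adjusted p = 2.33e-07), as-nuoM/nuoN at 1925 ± 468 against 108 ± 25.5 (log2 fold change 4.14, adjusted p = 1.58e-05), as-zwf, at the gene of glucose-6-phosphate dehydrogenase, at 7437 ± 305 against 765 ± 102 (log2 fold change 3.28, adjusted p = 5.18e-06) and as-ftsW, at a cell division gene, at 4169 ± 144 against 408 ± 224 (log2 fold change 3.47, adjusted p = 2.97e-05). The respiratory chain list rose in 19 of 20 (20 adjusted over the list alone) cases, 16 after quantile normalization and 16 after centring (median relative log2 fold change 1.44, camera adjusted p = 7.64e-04), the outer membrane list in 12 of 13 (13 adjusted over the list alone), 9 after quantile normalization and 10 after centring (median relative log2 fold change 1.02, camera adjusted p = 0.0179), the peptidoglycan list in 21 of 25 (22 adjusted over the list alone, where 1 fell), 16 after quantile normalization and 17 after centring (where 1 and 1 fell) (median relative log2 fold change 1.08, camera adjusted p = 0.00732), and the TCA cycle list in 16 of 23 (20 adjusted over the list alone), 12 after quantile normalization and 11 after centring (where 2 and 1 fell), with 1 decrease (median relative log2 fold change 0.84, camera adjusted p = 0.0411). Each of these 4 list calls had adjusted p = 0.997 with an estimated correlation, and the TCA cycle call was also lost without LB control 1 (adjusted p = 0.134). Spectinomycin libraries held 20.2% and 20.6% of their units in rRNA and 13.8% and 12.8% in RNAs listed antisense to tRNA genes. as-phoB fell from 8696 ± 875 to 355 ± 16.3 (log2 fold change -4.61, adjusted p = 5.30e-07), as-pstS had a log2 fold change of -4.94, and T1E_0388 fell from 1260 ± 59.4 to 30.5 ± 7.78 (log2 fold change -5.34, adjusted p = 8.68e-05). In all, 706 features rose and 158 fell, of which 677 and 145 changed at least 2-fold. Increases made up 81.7% of the calls, 56.8% of 910 after quantile normalization and 45.6% of 904 after centring. The number called was 439 without spectinomycin 1 and 567 without LB control 2.

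Among the features that rose with chloramphenicol, which binds the large ribosomal subunit, as-rh28, whose product the files do not name, stood at 2740.5 ± 288 against 245.5 ± 61.5 (log2 fold change 3.49, adjusted p = 6.78e-05). as-T1E_4073/T1E_4072, at a membrane sensor gene of signal transduction, stood at 10138.5 ± 2566 against 1136 ± 67.9 (log2 fold change 3.13, adjusted p = 6.78e-05). as-T1E_4697, at a porin gene, stood at 3619 ± 1864 and was listed at 0 in both LB control libraries (adjusted p = 0.00416). At the toluene efflux locus, as-ttgA stood at 3501 ± 142 against 1094 ± 52.0 (log2 fold change 1.68, adjusted p = 0.00249) and the TtgR row T1E_0244 at 6828 ± 1709.8 against 2595 ± 851 (log2 fold change 1.41, adjusted p = 0.0227). The multidrug efflux list had 2 of 14 (2 adjusted over the list alone) increases and was not called (camera adjusted p = 0.758). as-lon/hupB stood at 70603 ± 8144 against 21331.5 ± 1326 (log2 fold change 1.72, adjusted p = 0.00987). Ribosomal protein loci lay above the other antisense-listed RNAs, with 2 of 14 (7 adjusted over the list alone) increases, 1 after quantile normalization and 0 after centring (median relative log2 fold change 0.60, camera adjusted p = 0.0163). Peptidoglycan loci lay below them. Only as-murE, of precursor synthesis, fell among the 25 (3 adjusted over the list alone), at 544 ± 235 against 1458 ± 204 (log2 fold change -1.48, adjusted p = 0.0245), with 3 decreases after quantile normalization and 4 after centring (median relative log2 fold change -0.78, camera adjusted p = 0.00113). Both list calls had adjusted p = 0.997 with an estimated correlation. The ribosomal protein call was also lost after quantile normalization (adjusted p = 0.302), without LB control 1 (0.226) and without chloramphenicol 1 (0.0899).

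Among the decreases with chloramphenicol, as-T1E_2185, at an acyl-CoA dehydrogenase gene, had -2.34 on the log2 scale (adjusted p = 0.00115). The Hfq row (T1E_2597), of an RNA chaperone, was listed at 0 in both chloramphenicol libraries and at 33 ± 8.49 in LB control (adjusted p = 0.0138), a call lost without LB control 2 (0.0999), without chloramphenicol 2 (0.0515), with a pseudocount of 10 (0.0891) and after quantile normalization (0.119). In all, 120 features rose and 35 fell, of which 120 and 34 changed at least 2-fold. Increases made up 77.4% of the calls, 58.9% of 202 after quantile normalization and 52.0% of 152 after centring. Chloramphenicol 2 had 905 rows at 0, the most of any library, against 228 in chloramphenicol 1. Decreases of low genes may rest in part on that library. Without chloramphenicol 1 the fit called 508 features, 412 of them decreases, and without LB control 2 81. With only the 4 libraries of the comparison no feature was called by limma, and 645 had an unadjusted p under 0.05. Without LB control 2 the calls of as-murE (adjusted p = 0.163), T1E_0244 (0.194) and as-lon/hupB (0.0517) ended. That of T1E_0244 also ended without chloramphenicol 1 (adjusted p = 0.0714), and that of as-murE without chloramphenicol 2 (0.22).

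Kanamycin, an aminoglycoside given here at 1 µg/ml, came with higher RNAs at loci of respiration and the TCA cycle. as-sucB stood at 2380 against 122 ± 17.0 (log2 fold change 4.28, adjusted p = 5.12e-04), as-lpdG/sucB, of the same enzyme complex, at 2962 against 529.5 ± 2.12 (log2 fold change 2.48, adjusted p = 0.00474) and as-nuoM/nuoN at 979 against 108 ± 25.5 (log2 fold change 3.19, adjusted p = 0.00474). The respiratory chain list rose in 6 of 20 (19 adjusted over the list alone) cases, 4 after quantile normalization and 1 after centring (median relative log2 fold change 1.09, camera adjusted p = 9.58e-07), and the TCA cycle list in 7 of 23 (14 adjusted over the list alone), 6 after quantile normalization and 3 after centring (median relative log2 fold change 0.74, camera adjusted p = 3.55e-04). In the outer membrane list 0 of 13 (7 adjusted over the list alone) rose (median relative log2 fold change 0.55, camera adjusted p = 0.0389). Each of these 3 list calls had adjusted p = 0.997 with an estimated correlation, and the outer membrane call was also lost after quantile normalization (adjusted p = 0.0536) and without LB control 1 (0.134). In the kanamycin library rRNA held 31.9% of the units and RNAs listed antisense to tRNA genes 21.3%. The row of the pump gene T1E_0242 (TtgB) rose to 740 against 94.5 ± 0.71 (log2 fold change 2.96, adjusted p = 0.00474) and that of an AraC-type regulator, T1E_0252, to 1623 against 239 ± 70.7 (log2 fold change 2.79, adjusted p = 0.00474). as-T1E_2732, at a gene related to DNA photolyase, fell from 3328 ± 560.0 to 290 (log2 fold change -3.51, adjusted p = 6.96e-05). as-groEL stood at 1912.5 against 453.5 ± 44.5 (log2 fold change 2.08, adjusted p = 0.017), a call lost without LB control 2 (adjusted p = 0.0601). In all, 62 features rose and 19 fell, each at least 2-fold. Increases made up 76.5% of the calls, 59.8% of 82 after quantile normalization and 55.8% of 52 after centring. The single library was assumed to vary like the other groups. The number called was 23 without LB control 2, 141 without LB control 1 and 0 with only the libraries of the comparison, where 495 had an unadjusted p under 0.05 (limma).

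With ampicillin, a beta-lactam that blocks cell wall synthesis, 3 annotated genes and no antisense-listed RNA were called at the threshold. T1E_2690, a transglutaminase-like protein, stood at 59.5 ± 3.54 against 1.5 ± 2.12 (log2 fold change 4.92, adjusted p = 0.0145), a call that ended without LB control 2 (adjusted p = 0.0652), ampicillin 1 (0.203) or ampicillin 2 (0.339), and with a pseudocount of 0.1 (0.126) or 10 (0.0751). The other two called genes, T1E_0288 and T1E_0373, encode hypothetical proteins and are named after their values were seen. T1E_0288 stood at 74 and 61 and T1E_0373 at 61 and 68 in the ampicillin libraries, and both were listed at 0 in the LB control libraries (adjusted p = 0.00595 and 0.00331). All 3 genes were also called higher with ciprofloxacin, tetracycline, gentamicin, spectinomycin and kanamycin. With chloramphenicol and with rifampicin 2 of them were. Each comparison uses the same LB control libraries, where these genes stood at or near 0, so these calls are not independent of each other. The LB control libraries had 262 and 489 rows at 0, and the ampicillin libraries 75 and 95. Increases of low genes may therefore rest in part on the LB control libraries, which was not tested. The rows named as beta-lactamase were not called, with T1E_0103 at 74 ± 12.7 against 66.5 ± 17.7 (adjusted p = 1). Of the 25 RNAs listed antisense to peptidoglycan and beta-lactam response genes, 0 rose and 0 fell. The respiratory chain list was called higher (median relative log2 fold change 0.18, camera adjusted p = 0.0212), although 0 of its 20 RNAs passed the test singly or adjusted over the list alone. It had adjusted p = 0.997 with an estimated correlation and was lost after quantile normalization (adjusted p = 0.0930), without LB control 1 (0.424) and without ampicillin 2 (0.130). An unadjusted p under 0.05 was found for 236 features. The count rose to 55 without LB control 1 and fell to 1 without LB control 2 and to 0 without ampicillin 1, without ampicillin 2, with only the 4 libraries of the comparison (where 420 had an unadjusted p under 0.05) and with a pseudocount of 10. In simulated data with this design limma recovered 7.31% of features changed 2-fold, 41.9% of those changed 4-fold and 65.3% of those changed 8-fold. The simulated noise came from the pooled spread, which fell short of the difference between the LB control libraries, so real recovery may be lower.

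The 2 aminoglycosides differ in structure and were given at different concentrations, 2 µg/ml gentamicin and 1 µg/ml kanamycin, so their comparison mixes compound and dose. Among the features lower with gentamicin, T1E_0388, the major facilitator transporter, stood at 23 ± 5.66 against 6563 (log2 fold change -8.12, adjusted p = 5.11e-05), as-mgtB/T1E_0389 at 1364 ± 619 against 67894 (log2 fold change -5.71, adjusted p = 3.83e-05), as-T1E_5634/mgtC at 449.5 ± 79.9 against 14247 (log2 fold change -4.99, adjusted p = 2.01e-04) and as-T1E_2661, of phosphate transport, at 272 ± 48.1 against 4206 (log2 fold change -3.96, adjusted p = 6.00e-05). T1E_0242 (TtgB) was also lower, at 66 ± 14.1 against 740 (log2 fold change -3.48, adjusted p = 2.15e-04). Higher with gentamicin were as-T1E_4073/T1E_4072, at 20310 ± 4910.1 against 491 (log2 fold change 5.35, adjusted p = 1.71e-06), as-ttgC, at 4731 ± 1223 against 314 (log2 fold change 3.88, adjusted p = 2.48e-04), and as-groEL, at 11161 ± 2674 against 1912.5 (log2 fold change 2.52, adjusted p = 8.17e-04). Of the DNA repair loci, as-recX/recA, as-lexA-1 and as-recN were not called, and no list was tested in this comparison. The log2 difference was 0.03 (95% confidence interval -0.56 to 0.62) for as-recX/recA, 0.41 (95% confidence interval -0.34 to 1.16) for as-lexA-1 and 0.94 (95% confidence interval 0.18 to 1.69) for as-recN (adjusted p = 0.16). In all, 353 features were higher and 141 lower with gentamicin, 352 and 140 of them at least 2-fold. Increases made up 71.5% of the calls, 52.6% of 572 after quantile normalization and 27.3% of 644 after centring. With only the 3 libraries of the comparison limma called 0 features, and 972 had an unadjusted p under 0.05.

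Responses to different antibiotics were compared in 28 pairs across features, which are not independent replicates. With one antibiotic set against LB control 1 and the other against LB control 2, so that no control is shared, Pearson's r (mean of both assignments) was 0.46 for rifampicin and gentamicin, 0.42 for tetracycline with either of them and 0.39 for ciprofloxacin and gentamicin. It was 0.16 for kanamycin and rifampicin and -0.015 for chloramphenicol and ciprofloxacin, and the median of the 28 pairs was 0.135. Simulated unchanged groups gave r between -0.00076 and 0.0085. Against the same 2 controls r ran from 0.249 for chloramphenicol and ciprofloxacin to 0.794 for rifampicin and gentamicin (median 0.513), but unchanged groups simulated against shared controls gave 0.404 to 0.507 as well. The r with shared controls lay above the simulated one in 19 of the 28 pairs and below it in 9. The covariance lay above the simulated one in 28, by 0.083 to 1.34. The simulation drew its noise from a spread pooled over the groups, which fell short of the real difference between the control libraries. For ampicillin and chloramphenicol the covariance was 0.469 with shared controls, 0.380 in the simulation and -0.023 with separate controls. The excess over the simulation alone therefore does not show a shared response. With separate controls r was above 0 in both assignments in 26 pairs. Separate controls remove only what is particular to 1 control library. A difference in growth stage or batch that both LB control libraries share stays in each r. Rifampicin and gentamicin shared 720 increases and 251 decreases, and no feature was called in opposite directions. Independent lists would share 108 and 22.0, but lists called against the same LB control libraries are not independent. Simulated groups shared 0 and 0, because unchanged groups give almost no calls. Neither number separates a shared response from the shared controls, here or for the pairs below. Rifampicin and gentamicin shared 542 increases and 492 decreases after quantile normalization and 379 and 1167 after centring. Tetracycline and spectinomycin shared 625 increases and 122 decreases (97.9 and 10.3 for independent lists), with 1 feature in opposite directions, and 430 increases and 318 decreases after quantile normalization and 332 and 462 after centring. Ciprofloxacin and gentamicin shared 566 and 243 (117 and 35.7), with 36 in opposite directions, and 457 increases and 436 decreases after quantile normalization and 309 and 732 after centring. Chloramphenicol and ciprofloxacin shared 63 increases and 7 decreases (16.1 and 3.33), and 30 features went in opposite directions, among them as-lon/hupB, which had 1.72 and -1.87. The shared calls were 60 increases and 35 decreases after quantile normalization and 38 and 19 after centring. The balance of shared increases and decreases thus depended on the scaling. With each antibiotic against its own control library, rifampicin and gentamicin shared 510 and 509 increases and 145 and 147 decreases in the 2 assignments, and chloramphenicol and ciprofloxacin 23 and 47 increases and 3 and 3 decreases.

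Other lists were not called in any comparison with LB control. For RNAs listed antisense to their genes, the lowest camera adjusted p was 0.0725 for flagella and chemotaxis, 0.0827 for multidrug efflux, 0.0954 for amino acid biosynthesis, 0.124 for aromatic compound catabolism, 0.224 for ribosome assembly, rescue and hibernation and for transposases and integrases, and 0.311 for SOS response and DNA repair and for aminoacyl-tRNA synthetases. It was 0.325 for oxidative stress, 0.402 for general stress and stringent response, 0.423 for translation factors, 0.539 for envelope stress and alginate, 0.626 for RNA polymerase and sigma factors and 0.720 for DNA gyrase, topoisomerases and replication. Efflux RNAs rose in 11 of 14 (11 adjusted over the list alone) cases with rifampicin, 8 after quantile normalization and 7 after centring, and in 10 of 14 (10 adjusted over the list alone) with tetracycline, 8 after quantile normalization and 9 after centring (where 3 and 3 fell). Of these lists, 3 and 2 RNAs fell under the authors' scaling. Among the rows of annotated genes no list was called (camera, 0 of the 23 lists, lowest adjusted p = 0.0827 for the TCA cycle and central carbon with spectinomycin). Iron and siderophore uptake (0.653), prophage and pyocin genes (0.539) and type VI secretion (0.478) were tested on these rows alone, and toxin-antitoxin systems had too few members for a test.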

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

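These values concern ribosomal RNA, which the comparisons left out, and were listed because a group's mean was at least 4 times that of LB control with its libraries above both control libraries and a control mean of at least 1000. These limits were chosen after the data were seen, and no test was run. The 5S ribosomal RNA gene T1E_5758 stood at 1999820 ± 716526 with ciprofloxacin and 1552480 ± 134545 with rifampicin, against 370676 ± 115306 in LB control (5.40 and 4.19 times, n = 2 each). A second 5S ribosomal RNA gene, T1E_5823, stood at 26065 ± 2731 with ciprofloxacin against 6051 ± 3048 (4.31 times). The RNA listed antisense to T1E_5841, a small subunit ribosomal RNA gene, stood at 5937210 ± 2258360 with rifampicin and 6256710 ± 1472280 with gentamicin, against 1104160 ± 633889 (5.38 and 5.67 times).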

How the results depend on the processing

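Alternatives chosen after the data were seen were centring on the median antisense-listed RNA, separate rows, kanamycin as the mean of its files, and all those for the correlations except that of features above the lowest quartile by mean value. Counts within 1.5 times of those reported were found for each comparison without a filter, with rRNA kept, and with rows tested separately, and for kanamycin's 2 comparisons with the mean of its files (76 features against LB control, 459 for gentamicin against kanamycin). The counts that moved further are given by setting, and the cause was not tested except where the setting itself has fewer libraries.

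Quantile normalization gave 5 features for ampicillin. A pseudocount of 0.1 gave 5 and one of 10 gave 0 for ampicillin. Centring gave 52 for kanamycin, 2068 for gentamicin, 2078 for rifampicin and 2730 for tetracycline. The replicate block gave 50 for kanamycin. With only the libraries of the comparison, limma called 0 for ampicillin (420 at an unadjusted p under 0.05), 0 for chloramphenicol (645), 0 for kanamycin (495) and 0 for gentamicin against kanamycin (972), 388 for tetracycline and 736 for gentamicin. Such a fit has at most 2 residual degrees of freedom.

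Leaving out 1 library gave 0 to 55 features for ampicillin, 81 to 508 for chloramphenicol, 23 to 141 for kanamycin, 439 to 806 for spectinomycin, 864 to 1126 for gentamicin, 950 to 1171 for rifampicin, 958 to 1599 for tetracycline, 1110 to 1414 for ciprofloxacin and 338 to 442 for gentamicin against kanamycin. A group left with 1 library was assumed to vary like the others, and kanamycin's single library could not be left out. The median Pearson's r of the 28 pairs was 0.457 after quantile normalization, 0.683 without LB control 1, 0.564 without LB control 2 and 0.135 with each antibiotic of a pair against its own LB control library, which shares no control, and 0.517 for features above the lowest quartile.

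The 28 list calls fell to 0 with an estimated correlation. They were 26 with quantile normalization, 36 with centring and 22 to 36 when 1 library was left out. Of the calls reported, 24 held after quantile normalization, 28 after centring and 27 with the replicate block, where ribosomal proteins with tetracycline had adjusted p = 0.0529. When each library was left out in turn, calls held 96 times and ended 10 times.

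A called value of a named feature counted as kept if it stayed called in the same direction. An uncalled value counted as kept if it stayed uncalled, whatever its direction. Kanamycin as the mean of its files ended some calls of named features. Of 554 values, the number kept was 518 after quantile normalization (19 lost and 15 gained a call), 494 after centring (26 lost and 32 gained) and 453 with only the libraries of the comparison (99 lost and 2 gained). It was 545 with the block, 544 and 539 with pseudocounts of 0.1 and 10, and 1804 when each library was left out in turn (172 lost and 12 gained). The RNA listed antisense to gyrA reversed after quantile normalization and centring, to -0.12 and -0.16 with rifampicin and to -0.046 and -0.12 with gentamicin on the log2 scale. Planned size factors and a second test tool, meant for counts, were not run since the values are not counts. Depth is unknown, and n = 2 limits which changes can be called.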

Other observations

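Of the tests in this part, those on gene rows of 3 lists (aminoacyl-tRNA synthetases, translation factors, respiratory chain) were written before their result was seen, and the other 6 were chosen after the results were seen. Within the SOS and DNA repair list, 4 further antisense-listed RNAs were called with ciprofloxacin and 4 were not; they are outside the rule for named features and were chosen after their values were seen. The first 4 were antisense: recX, at 6622 and 6212 against 590 and 746 in the LB control libraries, antisense: ruvC, of Holliday junction resolution, at 5947 and 6433 against 867 and 984, antisense: dinG, of a helicase, at 8922 and 8147 against 3455 and 2495, and antisense: uvrD, of excision repair, at 4130.5 and 4154 against 2801 and 2356. Those not called were antisense: uvrB, at 2280 and 2020 against 1717 and 843, antisense: radA, antisense: ssb yajR and antisense: T1E_2795.

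In the gene sets compared, the rows of annotated genes had far lower medians than the RNAs listed antisense to genes of that set. Genes were not matched one by one. A candidate explanation is that the strand of the reads was assigned opposite to the annotated strand. In that case genes that growing cells express highly would have gene rows at or below the median, and the gene rows of the 3 lists above had a median of 40 in LB control, where all genes had 50. Transcription of the opposite strand in addition to the genes' own was assumed to leave them above the upper quartile, which was 102.5. They lay below it, but the limit is an assumption, so the values cannot exclude such transcription. Libraries without strand information would give tRNA genes and their antisense partners values of the same order, but the highest ratio of their medians in a library was 0.000703. How predicted RNAs came to be listed is not stated, and gene rows far above the median in LB control, such as those of the 5S ribosomal RNA genes T1E_5758 (370676) and T1E_5823 (6051), T1E_0244 (2595) and T1E_0388 (1260), go against it for those genes and stay open.

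Ciprofloxacin, tetracycline, rifampicin, gentamicin and spectinomycin stood apart from LB control in the rank order of antisense-listed RNAs. The authors' scaling, 1 factor per library, changes no ranks within a library, and the highest rank correlation of these groups with LB control was 0.443. Inhibition of translation as a cause shared by all ribosome inhibitors could not be decided. Chloramphenicol and kanamycin had a higher mean rank correlation with LB control than with tetracycline, gentamicin or spectinomycin, by at least 0.230. A weaker action of these 2 antibiotics at the doses given would produce the same order, and kanamycin had 1 library. An unlabelled batch that holds whole groups cannot be told apart from the antibiotics. No group had libraries on both sides (lowest rank correlation within a group 0.815). In the order of the samples LB control, ampicillin, chloramphenicol and kanamycin come first and the groups that stood apart come after. RNAs listed antisense to tRNA genes held 21.3% to 32.4% of the units in the former and 2.66% to 13.8% in the latter. Libraries of a group were not always nearest each other. Tetracycline 1 had 0.839 with gentamicin 2, and the LB control libraries (0.918) lay closer to ampicillin (0.936 to 0.957). Differences between the antibiotics and in how strongly each dose acted stay open and were not tested.

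The kanamycin files may be 1 table deposited 2 times with a constant added, since all 7482 rows differed by the same number. Separate sequencing of 2 libraries would spread the differences, but the commonest covered 100% of the rows here against at most 4.70% in the other pairs of libraries. For the kanamycin files no biological explanation was tested.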
